A study of Homo sapiens with 12 samples.

How the data were processed

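RNA of the lung adenocarcinoma lines CL1-0 and CL1-5, exposed to 0 or 300 mV/mm for 2 h in serum-free medium, was hybridised to 12 Affymetrix arrays of 54675 probe sets, 3 per line and field group. Per the labels' protocols, cells were taken from the microfluidic chip with trypsin, RNA was extracted with a column kit, and biotin-labelled cRNA was made from 10 µg of total RNA. The deposited values are signals in linear intensity units which, per the submitters' processing notes, came from the MAS5 algorithm. Its version, detection calls and filters are not given in the sources used here. The mean of the values of each array, with the lowest and highest 2% left out, was equal on all arrays (500.07 to 500.08), so arrays were not scaled further.

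Values under 1 (3691 values) were set to 1 and taken to log2. Probe sets above the median of their own array on at least 3 arrays were kept (31890). Of all probe sets, 41097 carry 1 gene symbol, 1801 several and 11777 none, and 62 are controls. Only those with 1 symbol were used for genes, each gene by its probe set with the highest mean log2 value, which left 13882 genes. The difference between groups was tested with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 with data.table (version 1.17.8), in a fit of 4 group means to all 12 arrays, at a Benjamini-Hochberg adjusted p of 0.05. The 6 comparisons were the field in each line, its average over the lines, its difference between the lines, and the lines with and without the field. The number of arrays limits the precision, and the median SE was 0.367 for a comparison of 2 groups.

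Gene lists, 39 in number with 1057 of 1156 entries on the array, were fixed with the tests, filters, alternatives and naming rule before the data were examined. They were tested with limma's camera (preset correlation of 0.01, lists of at least 5 genes), again with a correlation estimated per list, and with fry, which tests whether the genes of a list move, on balance, one way and does not compare the list with other genes. Members past the test were counted over all genes and adjusted over the list alone. Genes named are the 12 with the largest change in each direction among genes past the test whose groups do not overlap, the 10 with the smallest p where fewer than 10 passed, up to 4 list members with the largest change or 2 with the smallest p, and CDH1, VIM and EGFR as references. Only some of the genes that the rule allows are printed. A further reference, TERC, has no named probe set in the annotation used here. Genes printed from the fit with the replicate block were chosen after their values were seen.

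Replicate numbers were tested as pairs. After the group means were removed, arrays of the same number in a line correlated at 0.609, 0.346 and 0.363 in CL1-0 and 0.551, 0.423 and 0.187 in CL1-5. The highest correlation with another number was −0.382, 0.173 and 0.269 in CL1-0 and −0.322, 0.284 and 0.23 in CL1-5, above that of the same number for replicate 3 of CL1-5. The labels do not state whether the replicates are paired. In each line the largest of these correlations was that of replicate 1, whose arrays also lacked the poly-A spike-in signal, so a batch and pairing are not told apart. The replicate block is therefore given beside the unblocked fit. The alternatives set in advance were quantile normalization, arrays centred on their median, a pseudocount at the 10th percentile (5.05), no filter, a stricter filter (6 arrays above the 60th percentile), the mean of a gene's probe sets, eBayes without trend, only the groups compared, the replicate block, all probe sets, and leaving out each array in turn. Chosen after seeing the data were the poly-A spike-in batch as a block and only the arrays with or without that signal. Values below the array median set to it were chosen then too, and give the folds printed as at least a value. These folds are estimates and do not cover the spread over arrays.

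The steps were tested on simulated data made by changing 100 genes by 2-fold and 100 by 4-fold in the comparison of the field in CL1-5, in 5 runs. Without the block 8.2 and 47 of them were recovered on average with 0.2 false calls, and with the block 50.4 and 80.4 with 6.8 false calls. The simulated values were built from the fit with the replicate block, with noise drawn independently for each gene. Pairs therefore hold in them by construction, so the gain with the block cannot show whether the arrays are paired. Recovery on the arrays, where genes are correlated, may differ. Probe sets with no symbol or several were not used for genes.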

Results

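Messenger RNA levels were measured on 12 Affymetrix arrays in CL1-0 and CL1-5, human lung adenocarcinoma cell lines of common origin, of which CL1-5 is a more invasive subline. Cells in a microfluidic chip were kept for 2 h in serum-free medium under a direct-current electric field (EF) of 300 mV/mm or without a field (0 mV/mm). This gave 4 groups of 3 arrays, which the labels name biological replicates, and the comparisons asked how the lines differ and how each line responds to the field. The deposited values are linear array intensities, with a median between 60.7 and 72.4 on the 12 arrays, and the number of arrays limits the precision. Levels below are mean log2 signals with the SD over 3 arrays. Changes are log2 fold changes with the standard error (SE) of a limma fit to 13882 genes.

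The first principal component, with 55.2% of the variance, separated the cell lines. The second, with 18.5%, separated replicate 1 of all 4 groups from replicates 2 and 3. On these 4 arrays the poly-A spike-in dap, a control transcript added during labelling, gave a signal of 1.37 to 13.3, against 1644 to 2333 on the other 8 arrays, and the signal of 18S ribosomal RNA was 49.7 to 134.1 against 5577 to 8406. Each group held 1 array without and 2 arrays with the spike-in signal.

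**Figure D1:**
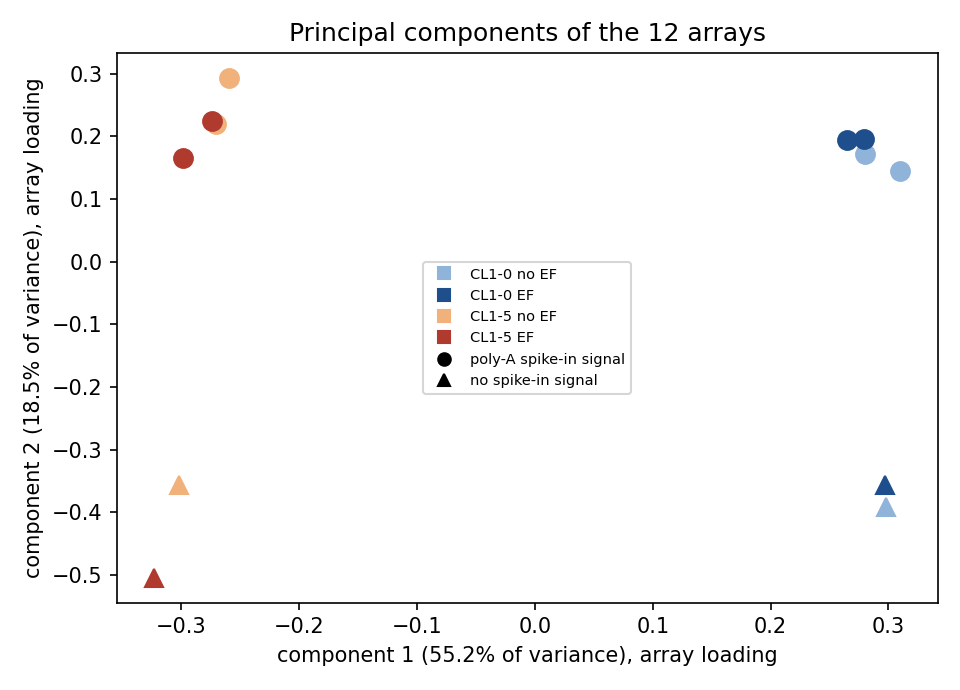
Loadings of the 12 arrays on the first component (horizontal, 55.2% of the variance, no unit) and the second component (vertical, 18.5%, no unit), with colours for the 4 groups. The 4 triangles are the arrays without poly-A spike-in signal, replicate 1 of each group, and lie below the 8 circles in both lines.

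Without a field, CL1-5 differed from CL1-0 most in genes that only 1 of the lines expressed well above the array median. PLAU, the urokinase plasminogen activator, reached 14.49 ± 0.24 in CL1-5 and 4.57 ± 1.35 in CL1-0 (adjusted p = 4.84e-07), and the collagenase gene MMP1 reached 13.78 ± 0.17 against 4.78 ± 1.34 (adjusted p = 6.57e-06). PAEP (glycodelin), the interleukin-8 gene CXCL8 and THBD (thrombomodulin) were higher in CL1-5 by 10.91 ± 0.48, 8.48 ± 0.45 and 9.91 ± 1.01 (SE, n = 3 per line). ALDH1A1, an aldehyde dehydrogenase that makes retinoic acid, was lower by −12.03 ± 0.44, the gap junction gene GJA1 by −11.23 ± 0.90 and the transcription factor SOX2 by −8.77 ± 0.34. With every value below its array's median raised to that median, the differences were at least 365-fold for PLAU, 213-fold for MMP1, 256-fold for PAEP, 237-fold for CXCL8, 179-fold for THBD, 251-fold for ALDH1A1, 333-fold for GJA1 and 183-fold for SOX2.

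The reference genes differed less. CDH1 (E-cadherin) lay at 9.22 ± 1.55 in CL1-0 and 5.77 ± 1.72 in CL1-5, a change of −3.46 ± 0.98 (adjusted p = 0.0295), or at least 6.56-fold with low values raised to the median. This call ended without replicate 2 or 3 of CL1-0 (adjusted p = 0.0927 and 0.123) or replicate 2 or 3 of CL1-5 (adjusted p = 0.0724 and 0.12). EGFR, the epidermal growth factor receptor, was higher by 2.14 ± 0.35 (adjusted p = 0.00122), and by 1.47 with an adjusted p of 0.242 when its probe sets were averaged. VIM (vimentin) changed by 0.27 ± 0.37 (adjusted p = 0.709), against 1.21 (adjusted p = 0.0187) with averaged probe sets.

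Interferon response genes were higher in CL1-5, with 28 of 39 past the test upward and 0 downward (31 and 0 adjusted over the list alone). The median difference was 2.71, and IFIT3 and MX1, both antiviral effectors, differed by 6.39 ± 0.76 and 6.25 ± 1.21, of which low values raised to the median leave at least 69.8-fold and 14.9-fold. The set test camera gave this list an adjusted p of 2.67e-16, and adjusted p = 0.203 with an estimated correlation. Antioxidant genes of the NRF2 list were lower in CL1-5, with 0 up and 15 of 28 down (0 and 16 adjusted over the list alone), a median of −1.15 and adjusted p = 9.33e-09. That call held at adjusted p = 0.0139 with an estimated correlation and ended at 0.0601 with that and the replicate block. AKR1C1 and GSR (glutathione reductase) fell by 2.69 ± 0.31 and 2.26 ± 0.36 between CL1-0 and CL1-5.

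Mesenchymal markers were also higher, with 13 of 23 up and 3 down (15 and 3 adjusted over the list alone), a median of 1.76, adjusted p = 2.49e-06, and adjusted p = 0.0339 with an estimated correlation (0.182 with that and the replicate block). SNAI2, a repressor of epithelial genes, differed by 7.68 ± 0.36 and the matrix protein gene SPARC by 5.93 ± 0.62, or at least 144-fold and 23.8-fold with low values raised to the median. Of 18 epithelial markers, 2 were higher and 3 lower, the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.746). Its lower members were SPINT2, EPCAM and CDH1, and the desmosomal gene DSP was higher by 2.96 ± 0.29.

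Matrix metalloproteinase and plasminogen genes were higher, with 11 of 18 up and 1 down over all genes and adjusted over the list alone (adjusted p = 2.49e-06, and adjusted p = 0.0647 with an estimated correlation). Besides PLAU and MMP1 they included PLAUR, the urokinase receptor, at 4.78 ± 0.29. Metallothioneins, which bind zinc and copper, had 6 of 9 up and 0 down in both counts (adjusted p = 2.49e-06, and adjusted p = 0.12 with an estimated correlation), led by MT1H at 4.13 ± 0.52. NF-kB and inflammatory cytokine genes had 12 of 23 up and 1 down in both counts (adjusted p = 9.64e-06, and adjusted p = 0.0647 with an estimated correlation), with IL6 higher and CCL2 lower, at least 27.2-fold and 2.34-fold with low values raised to the median. Wnt target genes had 9 of 18 up and 0 down in both counts (adjusted p = 9.22e-05, and adjusted p = 0.0647 with an estimated correlation), including CD44, at least 112-fold higher by the same measure, and the cyclin gene CCND1 at 5.59 ± 0.36. Endothelial markers, fixed as a list for another cell type, had 5 of 9 up and 0 down (6 and 0 adjusted over the list alone), with adjusted p = 9.22e-05 and adjusted p = 0.0647 with an estimated correlation. Their members TIE1 and ESAM were at least 4.48-fold and 7.86-fold higher with low values raised to the median.

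Integrins, collagens and laminins, apoptosis regulators, immediate early genes, hypoxia and glycolysis, antigen presentation and ERK feedback genes passed camera upward, and ribosome biogenesis and MYC targets downward, with adjusted p from 0.000917 to 0.0457 and from 0.142 to 0.774 with an estimated correlation. Over all genes the numbers up and down were 8 and 2 of 27 integrin genes (13 and 2 adjusted over the list alone), 12 and 5 of 30 matrix genes (13 and 5), 10 and 2 of 32 apoptosis regulators (11 and 3) and 12 and 4 of 32 immediate early genes (13 and 5). They were 8 and 2 of 38 hypoxia genes (9 and 2 adjusted over the list alone), 6 and 1 of 16 antigen presentation genes (6 and 2), 5 and 2 of 16 ERK genes (5 and 2) and 0 and 6 of 27 MYC targets (0 and 6). Among their members, ITGB3, LAMB3, IER3 and NDRG1 were higher by 5.61 ± 0.44, 7.78 ± 0.87, 4.55 ± 0.36 and 5.03 ± 0.55, where low values raised to the median leave at least 42.2-fold for ITGB3 and 85.3-fold for LAMB3. SLC2A3, a glucose transporter gene in the hypoxia list, was lower by −4.10 ± 0.39. The telomerase gene TERT, in the MYC target list, was lower by −3.31 ± 0.89 (adjusted p = 0.0226), or at least 4.59-fold with low values raised to the median. Its call ended without replicate 1 or 3 of CL1-0 (adjusted p = 0.0823 and 0.0542) or replicate 2 or 3 of CL1-5 (0.078 and 0.0554). Without replicate 1 of CL1-5 the calls of the immediate early, ERK, hypoxia, antigen presentation and MYC target lists ended (adjusted p = 0.1, 0.143, 0.618, 0.112 and 0.112), and the ERK and hypoxia medians changed sign, from 0.43 to −0.05 and from 0.18 to −0.06. On the spike-in arrays alone, which leave out replicate 1 of every group, the medians were 0.305 for ERK (adjusted p = 0.0222) and 0.0911 for hypoxia (adjusted p = 0.224). Those of the ERK, hypoxia and antigen presentation lists ended without replicate 2 of CL1-0 (0.146, 0.0702 and 0.0894), those of ERK and antigen presentation without replicate 3 of CL1-0 (0.0935 and 0.0639), that of antigen presentation without replicate 2 of CL1-5 (0.0813) and that of MYC targets without replicate 1 of CL1-0 (0.153).

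In all, 2492 genes passed an adjusted p of 0.05, 1253 higher and 1239 lower in CL1-5, and 1964 of them differed more than 2-fold. Arrays of the lines did not overlap for 2487 of these and for 4713 of all genes (34%, against 10% by chance). With replicate number as a block, 4926 genes passed (2319 higher and 2607 lower), and 4852 passed with the spike-in batch as a block. Within the batch with spike-in signal alone 4284 genes passed, and the batch without it held 1 array per group.

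**Figure D2:**
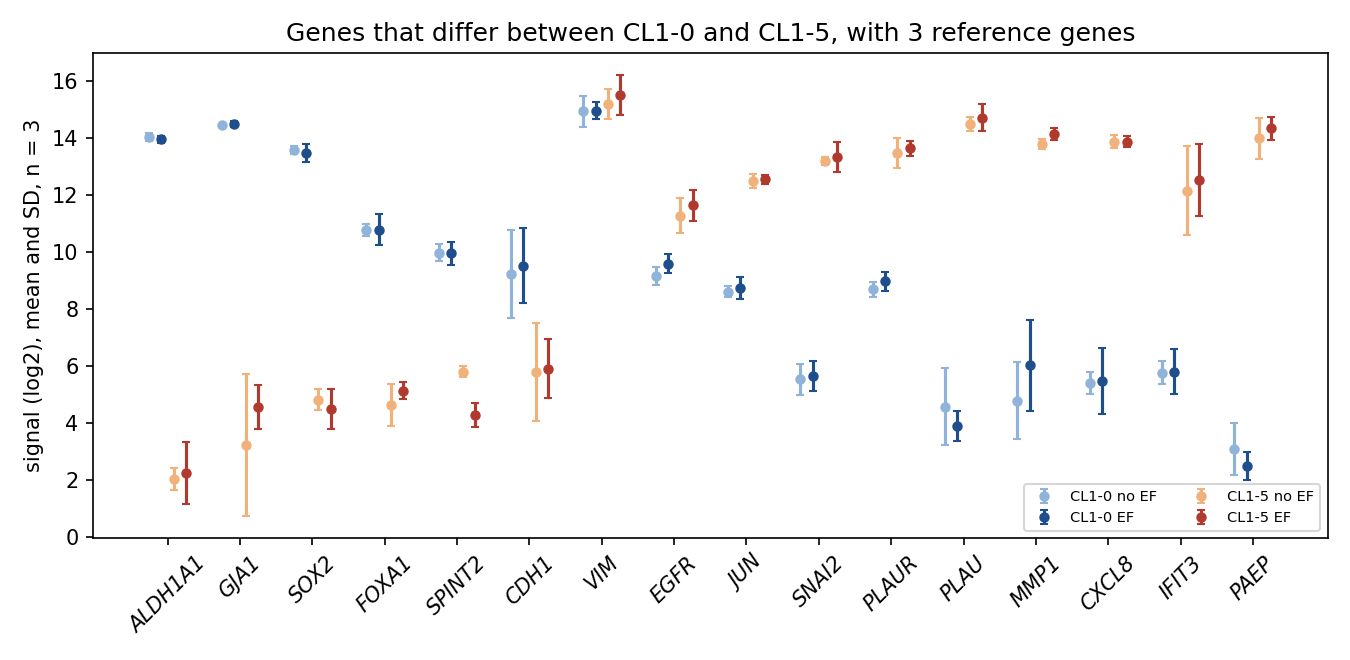
Mean log2 signal (vertical) of 16 genes (horizontal) in the 4 groups, with bars of 1 SD over 3 arrays. Without a field PLAU lay at 4.57 in CL1-0 and 14.49 in CL1-5, ALDH1A1 at 14.04 and 2.01, and the reference gene VIM at 14.93 and 15.20.

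Under the field, the lines differed in much the same way. PAEP and PLAU were higher in CL1-5 by 11.87 ± 0.48 and 10.83 ± 0.54, and the peptidase gene ANPEP and the ecto-nucleotidase gene NT5E by 9.32 ± 0.67 and 8.46 ± 0.78. ALDH1A1 was lower by −11.73 ± 0.44, the neuronal cytoskeleton gene MAP2 by −10.30 ± 0.56 and SOX2 by −9.0 ± 0.34. With low values raised to the array median these were at least 314-fold for PAEP, 406-fold for PLAU, 62.2-fold for ANPEP, 123-fold for NT5E, 243-fold for ALDH1A1, 130-fold for MAP2 and 172-fold for SOX2. CDH1 was lower by −3.61 ± 0.98 (adjusted p = 0.0226), at least 9.13-fold with low values raised to the median, a call which ended without replicate 2 or 3 of CL1-0 (adjusted p = 0.0771 and 0.0923) or replicate 2 of CL1-5 (adjusted p = 0.0838). EGFR was higher by 2.05 ± 0.35 (adjusted p = 0.00162, and 0.143 with averaged probe sets). VIM changed by 0.55 ± 0.37 (adjusted p = 0.352, and 0.00623 with the replicate block), and by 1.38 (adjusted p = 0.00921) with averaged probe sets.

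Interferon response genes had 33 of 39 up and 0 down (36 and 0 adjusted over the list alone), a median of 2.88 and adjusted p = 1.37e-18, with adjusted p = 0.162 with an estimated correlation. NRF2 genes had 0 up and 14 of 28 down (1 and 19 adjusted over the list alone) and mesenchymal markers 13 of 23 up and 3 down (14 and 3 adjusted over the list alone). Their adjusted p values were 7.33e-09 and 1e-05, and both calls held with an estimated correlation (adjusted p = 0.0133 and 0.0464), but not with that and the replicate block (0.0652 and 0.187). Lung epithelial lineage genes passed only here, with 2 of 16 up and 4 down in both counts and adjusted p = 0.0355 (adjusted p = 0.155 with an estimated correlation, and 0.0556 with the replicate block). FOXA1, a lung lineage transcription factor, was lower and its relative FOXA2 higher, at least 26.6-fold and 5.5-fold with low values raised to the median. Without the field the list had adjusted p = 0.118, and the difference between the settings, which equals the difference of the field response between the lines, had adjusted p = 0.746. The remaining lists called here were also called without the field, and each lost its call with an estimated correlation (adjusted p from 0.0758 to 0.681), hypoxia among them with a median of 0.50 (10 of 38 up and 2 down, 11 and 2 adjusted over the list alone, adjusted p = 0.000494, and adjusted p = 0.681 with an estimated correlation). The ERK list lost its call without replicate 2 or 3 of CL1-0 or replicate 1 of CL1-5 (adjusted p = 0.0506, 0.0815 and 0.104), and the MYC target list without replicate 3 of CL1-5 (0.0852).

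Here 2699 genes passed, 1362 higher and 1337 lower, 2078 of them by more than 2-fold and 2691 without overlap of the lines, and 4970 of all genes did not overlap (35.8%, against 10% by chance). The replicate block gave 5289 (2408 higher and 2881 lower), the spike-in batch as a block 5207 and the batch with spike-in signal alone 4416. The comparisons with and without the field share no arrays. They shared 1033 higher and 955 lower genes, where independent lists of these sizes would share 122.9 and 119.3, and 0 genes were called in opposite directions. Over all genes, which are not independent replicates, the line differences with and without the field correlated at Pearson's r of 0.898 and Spearman's rho of 0.79.

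The field changed no single gene past the threshold in CL1-5, and 8 gene lists passed camera with its preset correlation, with 0 past it with an estimated correlation and 0 with fry. Hypoxia and glycolysis genes had a median change of 0.28 with the field, with 35 of 38 members above 0. DDIT4, an inhibitor of mTOR signalling, and ADM, which encodes the vasodilator adrenomedullin, had the smallest p of the list at 0.68 ± 0.31 and 0.87 ± 0.43. ADM was 0.88, 0.78 and 0.97 higher in the 3 replicate pairs. Camera gave the list adjusted p = 6.34e-06, and adjusted p = 0.677 with an estimated correlation. Ribosomal protein genes had a median of 0.27 with 32 of 35 above 0 (adjusted p = 1.39e-09, and adjusted p = 0.677 with an estimated correlation), and RPL38 and RPS9 changed by 0.27 ± 0.15 and 0.23 ± 0.14. The ribosomal shift was 0.00 under quantile normalization (median 0.00429, adjusted p = 0.818), and oxidative phosphorylation genes lost their call there too (adjusted p = 0.232).

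Cell cycle genes lay lower. G2/M and mitosis genes had a median of −0.26 with 3 of 40 above 0 (adjusted p = 3.6e-05), and G1/S and DNA replication genes −0.24 with 3 of 37 above 0 (adjusted p = 8.66e-05), both with adjusted p = 0.677 with an estimated correlation. The mitotic kinase gene CDK1 changed by −0.46 ± 0.22 and PLK4, which drives centriole duplication, by −0.41 ± 0.20. The G2/M median was 0.07, 0.18 and −0.93 in replicate pairs 1, 2 and 3, so the lower median came from pair 3. Antigen presentation genes had a median of 0.36 with 14 of 16 above 0, oxidative phosphorylation genes 0.145 with 27 of 32, and unfolded protein and ATF4 response genes 0.19 with 21 of 33 (adjusted p = 0.000777, 0.000777 and 0.00602, each with adjusted p = 0.677 with an estimated correlation). HLA-E, of antigen presentation, and ASNS (asparagine synthetase), of the ATF4 response, changed by 0.50 ± 0.24 and 0.49 ± 0.20. Interferon response genes had a median of 0.20 with 28 of 39 above 0 (adjusted p = 0.0137, and adjusted p = 0.945 with an estimated correlation), and pair medians of 0.11, −0.99 and 1.57. IFI27 rested on pair 3, at 6.99 against 1.28 and 0.61, and its change of 2.96 ± 1.25 was 1.86 with low values raised to the median.

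None of the members of these 8 lists passed the test without the block, over all genes or adjusted over the list alone. With the replicate block 0 passed over all genes, while 19 of 35 ribosomal protein genes, 10 of 38 hypoxia genes, 2 of 33 unfolded protein genes and 1 of 16 antigen presentation genes passed upward adjusted over the list alone. These counts come from the same values as the list calls and are no separate evidence. The ribosomal median was 0.00429 under quantile normalization. Without the block and adjusted over the list alone, SPINT2, an inhibitor of serine proteases, passed downward among epithelial markers (−1.52 ± 0.32), a list with a median of 0.07 and a test direction downward (adjusted p = 0.932), and MT3 among metallothioneins (−3.92 ± 1.15). The 10 genes with the smallest p included these 2, ZNF300 at −2.69 ± 0.51, ZNF518B at 2.89 ± 0.65 and PROM1 at 2.96 ± 0.72, all with levels near or below the array median in both groups. With values below that median raised to it, ZNF300, SPINT2, ZNF518B and PROM1 changed by −0.02 each and MT3 by −0.67. CDH1, VIM and EGFR changed by 0.13 ± 0.98, 0.31 ± 0.37 and 0.37 ± 0.35.

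With limma, 0 genes passed, 258 had an unadjusted p under 0.05 where chance gives 694, and the groups did not overlap for 786 genes (5.66%, against 10% by chance). Both chance values hold for exchangeable arrays, and the replicate 1 arrays, which stand apart, widen the spread within groups (median SE 0.367, and 0.203 with the replicate block). With the replicate block 0 genes passed, with 1488 at an unadjusted p under 0.05 against the 694 that chance gives, and 12 lists passed. The block added Wnt targets, TGF-beta targets and immediate early genes upward and cholesterol and fatty acid synthesis genes downward (adjusted p = 0.0211, 0.0211, 0.0348 and 0.0162). In that fit these had adjusted p = 0.664, 0.789, 0.789 and 0.664 with an estimated correlation, where 0 of the 12 lists passed. Fry, which was run without the block, called 0 lists. The list medians in the spike-in batch with signal and in the batch without were 0.33 and 0.19 for hypoxia, 0.18 and 0.50 for ribosomal proteins, −0.40 and 0.07 for G2/M, −0.34 and −0.02 for G1/S, and 0.38 and 0.33 for antigen presentation.

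Over 14 alternatives each, the adjusted p ranged from 1.93e-14 to 0.954 for hypoxia (past 0.05 in 10), 1.12e-16 to 0.954 for ribosomal proteins (10), 3.54e-12 to 0.966 for G2/M (10), 1.34e-10 to 0.954 for G1/S (10) and 1.48e-19 to 0.994 for interferon (8). Each of the 8 list calls ended without at least 1 array. Without replicate 1 with the field, hypoxia, ribosomal proteins and the unfolded protein list had adjusted p of 0.536, 0.693 and 0.693, and without replicate 2 without the field hypoxia, G1/S and the unfolded protein list had 0.713, 0.64 and 0.332. Without replicate 3 with the field, G2/M, G1/S and interferon had 0.966, 0.428 and 0.801. Without replicate 3 without the field, G2/M, antigen presentation, interferon and the unfolded protein list had 0.281, 0.275, 0.218 and 0.09. The remaining losses were interferon and oxidative phosphorylation without replicate 1 without the field (0.272 and 0.234), and oxidative phosphorylation without replicate 2 with the field (0.0769).

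**Figure D3:**
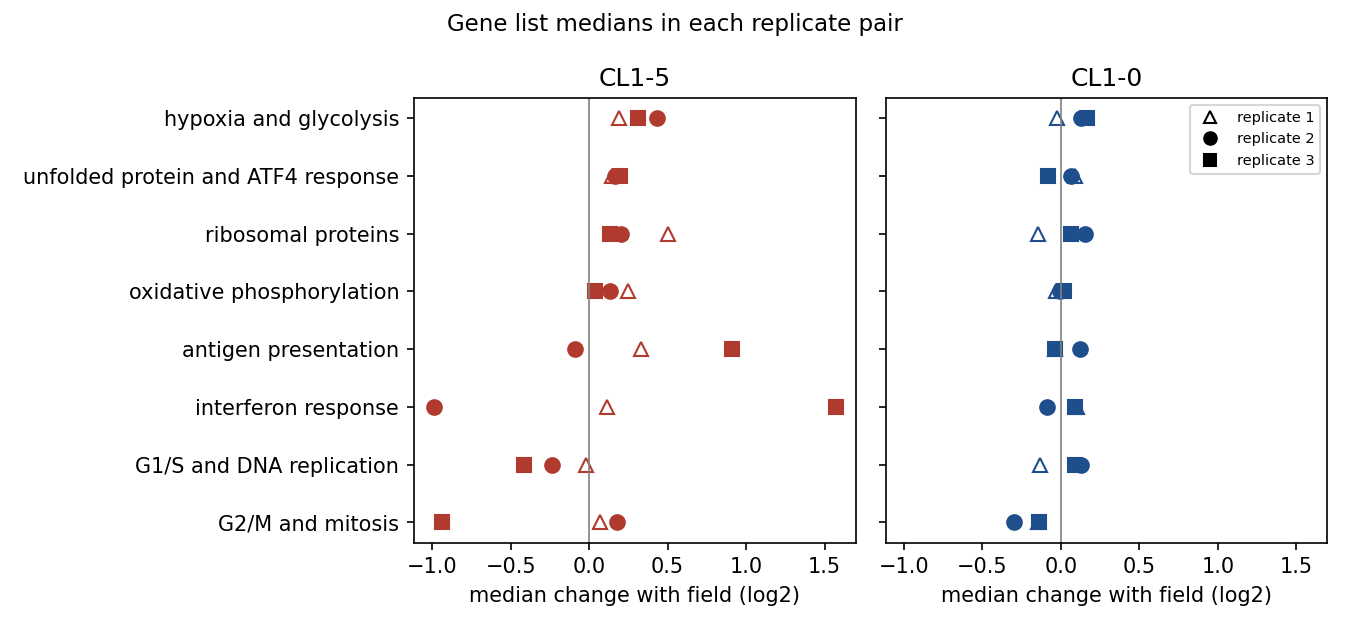
Median log2 change with the field (horizontal) of 8 gene lists (vertical) in each replicate pair of CL1-5 (left) and CL1-0 (right), 1 symbol per pair. In CL1-5 the hypoxia medians were 0.193, 0.429 and 0.314, while the interferon medians ran from −0.989 to 1.57.

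In CL1-0 the field likewise changed no single gene past the threshold. G2/M and mitosis genes had a median of −0.17 with 1 of 40 above 0, and medians of −0.14, −0.30 and −0.14 in the 3 pairs (adjusted p = 1.7e-05, and adjusted p = 0.779 with an estimated correlation). CDC25C, a phosphatase that activates CDK1, changed by −0.41 ± 0.26 and the kinesin gene KIF20A by −0.53 ± 0.35. Wnt target genes had a median of 0.185 with 11 of 18 above 0 (adjusted p = 0.0247, and adjusted p = 0.448 with an estimated correlation). Its member LEF1, a transcription factor of that pathway, lay below the array median in both groups (2.85 ± 0.50 and 5.08 ± 0.87) and changed by 0.06 with such values raised to the median. The Wnt call ended with the replicate block (adjusted p = 0.0547), while mesenchymal markers and Notch pathway genes passed with it (adjusted p = 0.0441 for both, and adjusted p = 0.8 for both with an estimated correlation), each with 0 members past the test over all genes and 1 adjusted over the list alone. Under quantile normalization Wnt targets had adjusted p = 0.0579. HOXD10 and CFAP99 had the smallest p, at 1.71 ± 0.33 and −3.11 ± 0.80, which came to 0.17 and 0.01 with values below the array median raised to it. CDH1, VIM and EGFR changed by 0.29 ± 0.98, 0.03 ± 0.37 and 0.45 ± 0.35.

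Limma called 0 genes, with 133 at an unadjusted p under 0.05 and 480 without overlap (3.46%, against 10% by chance), and the replicate block 0, with 467 at an unadjusted p under 0.05. Of 39 lists 2 passed and 0 passed with fry, and over 14 alternatives the adjusted p ranged from 9.18e-07 to 0.986 for G2/M and from 0.00701 to 0.986 for Wnt targets. The G2/M call ended without replicate 2 without the field (adjusted p = 0.139), and the Wnt call without replicate 2 or 3 without the field (0.0546 and 0.516) or replicate 1 or 2 with it (0.0743 and 0.154).

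Averaged over both lines, the lists that passed the preset test with the field included lower G2/M genes (median −0.23, 1 of 40 above 0) and higher hypoxia genes (0.17, 35 of 38), Wnt targets (0.24, 16 of 18) and ribosomal protein genes (0.14, 34 of 35). Their adjusted p values were 2.3e-10, 1.39e-06, 0.000401 and 7.39e-08, with adjusted p = 0.399, 0.627, 0.399 and 0.627 with an estimated correlation. AURKB, a mitotic kinase gene, changed by −0.38 ± 0.18, and DDIT4 by 0.49 ± 0.22. G1/S genes and cholesterol synthesis genes were lower (adjusted p = 0.00114 and 0.0395), and antigen presentation, unfolded protein and oxidative phosphorylation genes and mesenchymal markers higher (adjusted p = 0.012, 0.0395, 0.0395 and 0.046), with adjusted p from 0.399 to 0.651 with an estimated correlation. Fibroblast markers (−0.21, adjusted p = 0.0395) and interferon genes (0.15, adjusted p = 0.046) lost their calls with the replicate block (adjusted p = 0.105 and 0.068), and had adjusted p = 0.399 and 0.802 with an estimated correlation. Limma called 0 genes without the block (136 at an unadjusted p under 0.05) and 0 with it (768), and fry without the block called 0 lists. Camera called 12 lists without the block and 11 with it, and 10 lists were called in both. Under quantile normalization the ribosomal and oxidative phosphorylation lists (adjusted p = 0.555 for both, medians 0.01 and 0.02), mesenchymal markers (0.112), the unfolded protein list (0.0583) and interferon genes (0.1) lost their calls. With the replicate block 5 hypoxia and 2 unfolded protein genes passed adjusted over the list alone and 0 over all genes. The G2/M and Wnt lists kept their calls without each array in turn. The CL1-5 share of the lower G2/M median came from pair 3, with pair medians of 0.07, 0.18 and −0.93. In CL1-0 they were −0.14, −0.30 and −0.14. Hypoxia lost its call without replicate 2 of CL1-5 without the field or replicate 1 with it (adjusted p = 0.274 and 0.133), ribosomal proteins without the latter (0.451), and G1/S without replicate 2 of CL1-5 without the field, replicate 1 of CL1-0 with it or replicate 3 of CL1-5 with it (0.525, 0.113 and 0.27). The remaining lists each lost their call without 5 to 9 of the 12 arrays (adjusted p from 0.0512 to 0.834).

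The field response itself was compared between the lines. Ribosomal protein, oxidative phosphorylation, antigen presentation and hypoxia genes lay higher with the field in CL1-5 than in CL1-0 by the preset test, by medians of 0.244, 0.141, 0.317 and 0.174, and G1/S genes lay lower by −0.25 (adjusted p = 0.000138, 0.0141, 0.0244, 0.0446 and 0.0186, each with adjusted p = 0.906 with an estimated correlation). The adherens junction gene NECTIN1 changed by −1.04 ± 0.31 in CL1-5 and 0.50 ± 0.31 in CL1-0, a difference of −1.54 ± 0.44, and the potassium channel gene KCNQ1 by 1.42 ± 0.65 and −1.72 ± 0.65, a difference of 3.14 ± 0.92 that was 1.28 with values below the array median raised to it. Neither passed the test. Limma called 0 genes (150 at an unadjusted p under 0.05) and 0 with the replicate block (1002). Fry without the block called 0 lists, and camera with the replicate block called 6, including the 5 called without it. Across genes, which are not independent replicates, the field effects of the lines correlated at r of −0.0352 and rho of −0.0583, and 46.8% of genes had the same sign. Under quantile normalization only the G1/S difference passed (adjusted p = 0.0106). The ribosomal difference was −0.02 there (adjusted p = 0.774), and hypoxia, antigen presentation and oxidative phosphorylation had adjusted p = 0.597, 0.16 and 0.396. The 5 list differences each ended without at least 1 array, all of them without replicate 1 of CL1-5 with the field (adjusted p = 0.833 for hypoxia, 0.169 for antigen presentation and G1/S, 0.927 for ribosomal proteins and 0.0588 for oxidative phosphorylation). Without replicate 1 of CL1-0 without the field, the adjusted p was 0.477 for hypoxia, 0.246 for antigen presentation, 0.0567 for G1/S and 0.239 for ribosomal proteins. Without replicate 3 of CL1-0 without the field it was 0.0787, 0.0757 and 0.18 for hypoxia, antigen presentation and G1/S, and 0.0787 for oxidative phosphorylation, and without replicate 2 of CL1-0 with the field 0.291, 0.0631 and 0.421 for hypoxia, antigen presentation and G1/S. Further losses followed without replicate 2 of CL1-5 without the field (hypoxia 0.617, G1/S 0.713), replicate 3 of CL1-5 without (hypoxia 0.231, antigen presentation 0.429) or with the field (antigen presentation 0.102, G1/S 0.728) and replicate 1 of CL1-0 with the field (hypoxia 0.0721). Oxidative phosphorylation also lost its call without replicate 2 of CL1-0 or replicate 1 of CL1-5 without the field, or replicate 1 of CL1-0 or replicate 2 of CL1-5 with it (0.182, 0.289, 0.534 and 0.11).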

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

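Chosen after the results were seen were the tests of the spike-in batch, degraded RNA, the hypoxia and ribosomal lists and the 4 counts of single genes with the field in splits of the arrays, and the alternatives with the batch; the other splits, the exchanges within pairs and the TFPI2 tests were chosen before. Ribosomal protein, oxidative phosphorylation, antigen presentation and hypoxia genes lay higher with the field in CL1-5 than in CL1-0, by medians of 0.244, 0.141, 0.317 and 0.174, and G1/S genes lower, at −0.246, by a test of the difference itself. The preset test passed for each, with adjusted p = 0.906 with an estimated correlation for all 5, and under quantile normalization only G1/S passed (adjusted p = 0.0106, the others from 0.16 to 0.774).

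Replicate 1 arrays of all 4 groups stood apart on the second component. The lowest dap spike-in signal of the other 8 arrays was 123.6 times the highest of these 4, so a separate labelling or preparation batch may explain it. Degraded RNA on these arrays stays open, since the GAPDH 3' over 5' ratio lay above all other arrays on 3 of the 4 and the ACTB ratio on 1 of the 4. Replicate 1 of CL1-5 with the field had the highest of both, 1.54 for ACTB and 1.02 for GAPDH, against at most 1.32 and 0.953 on the other 8 arrays. A biological difference between the replicates was not tested.

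Hypoxia and ribosomal protein genes lay higher with the field in CL1-5 in 3 of 3 pairs each, relative to the median of all genes, which argues against 1 pair alone, and without pair 1 altogether their medians were 0.328 and 0.177. Leaving out 1 array of a pair also unbalances the spike-in batch, and without replicate 1 with the field, the array with the highest 3' over 5' ratios, the medians were 0.0392 and 0.0238, and hypoxia 0.0287 without replicate 2 without the field. Correlated genes moving with replicate noise cannot be told apart from an effect of the field for hypoxia, since only 1 of 4 arrangements, the real one at 0.279, was as large (highest other 0.233) and 4 are too few. Quantile normalization left the hypoxia median at 0.2166 of 0.279, and the list kept its call in the preset test (adjusted p = 0.0159, against 6.34e-06 before). It thus removed only part of the shift. The test asked for a median above the highest other, 0.233. That value came from arrangements without quantile normalization, so it decides nothing, and scaling of bright genes stays open for hypoxia. Scaling between arrays may explain the ribosomal shift, whose median was 0.00429 under quantile normalization, and a response to the field stays open for both.

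TFPI2, which encodes an inhibitor of serine proteases, was higher with the field in all 6 replicate pairs, by 1.55 on average (SD 0.511, lowest 1.2), but limma with the replicate block gave adjusted p = 0.296. In CL1-5 it lay below the array median (3.35 without and 5.09 with the field), and with such values raised to the median it changed by −0.02 there and by 1.36 in CL1-0. Its other probe set rose in 5 of 6 pairs by 0.223 on average (SD 0.944), so noise or cross-hybridisation of a single probe set may explain it. Chance was not excluded, since 3 of 32 arrangements of field and no field within pairs, the real one included, gave a gene with as large a lowest difference (1.2, highest other 1.67). A response to the field stays open.

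For the field in each line and for the lines, the 10 splits of 6 arrays are too few for a share under 0.05. Single numbers in brackets below count the splits that gave as many, the real one included. For genes, the real split and the highest other gave 0 and 0 in CL1-5 and 0 and 1 in CL1-0 (all 10 splits match a real count of 0, so nothing is tested), 2492 and 0 between the lines without the field (1) and 2699 and 0 with it (1). For lists they gave 8 and 12 in CL1-5 (3), 2 and 7 in CL1-0 (8), 16 and 15 between the lines without the field (1) and 17 and 17 with it (2). Splits that, like the real one, part all 3 pairs gave up to 6 lists in CL1-5 and up to 4 in CL1-0. For the average and the difference, the real split gave 0 genes, which all 100 splits match by construction (100 of 100 for both), so splits test nothing there. For lists chance was not excluded, with 10 and 68 of 100 splits, the real one included, giving as many as the real 12 and 5 (highest other 17 for both). Most of the 100 splits part fewer pairs than the real one, so they differ from it in design. The highest other gene count was 1934 in both, which used the same splits and so are not separate evidence. It came from splits with the replicate 1 arrays on one side in both lines. Of 14 splits of that kind, only 2 for the average and 1 for the difference called over 100 genes, and no split of another kind did. These few point to the spike-in batch as a structure of the arrays. With that batch as a block 0 genes passed for the average and 0 for the difference, with 410 and 597 at an unadjusted p under 0.05. The 17 other splits that part all 6 pairs gave 0 genes and up to 10 lists. That is below the real 12 for the average and above the real 5 for the difference, and these splits are too few for a share under 0.05. Of 32 arrangements within pairs, the real one included, 9 gave as many genes at an unadjusted p under 0.05 for the average with the replicate block as the real 768 (highest other 1025). For the difference 2 gave as many (1002 and 1025), and 9 gave as many genes moving the same way in all 6 pairs (490 and 694). Chance was not excluded. Some arrangements exchange only pairs of CL1-0 and keep the whole response of CL1-5. Exchanging all pairs of CL1-0 turns the average into the difference. A response of a single line could therefore raise the other arrangements too, and these counts cannot decide whether there was such a response.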

How the results depend on the processing

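The batch alternatives and the values floored at the array median were chosen after the data were seen. For genes, only called genes that the naming rule picked were followed, mostly for their large changes, in 167 results. Their share kept does not stand for all called genes. Of their 3166 values under alternatives 3086 kept their direction and side of the threshold, 80 no longer passed and 0 reversed. All are from the line comparisons, as the unblocked fit called 0 genes with the field. Of 1002 list values 754 kept both, 240 no longer passed and 8 reversed, all 8 in field comparisons. Kept and lost were 84 and 34 in CL1-5 and 17 and 13 in CL1-0. They were 151 and 100 for the average and 61 and 39 for the difference. Between the lines they were 209 and 31 without the field and 232 and 23 with it. Reversed means that the set test changed direction, so a median can change sign uncounted. On arrays without spike-in signal only the direction was compared. The causes of lost and reversed values were not tested here, and some settings have fewer arrays. Lists called were 0 in each field comparison with an estimated correlation and with fry, and 2 and 2 for the lines with an estimated correlation. For CL1-0 they were 1 with quantile normalization, 1 without a filter, 1 with the batch as a block and 7 on spike-in arrays; for the average 7 with quantile normalization and 5 without a filter; for the difference 1 and, on spike-in arrays, 8. Genes called between the lines without and with the field were 4926 and 5289 with the replicate block, 4852 and 5207 with the batch as a block, 4284 and 4416 on spike-in arrays and 3864 and 4286 as probe sets. Leaving out each array in turn gave 0 to 0 genes in CL1-5, 0 to 1 in CL1-0, 0 to 0 for the average and the difference, 1726 to 2221 and 1838 to 2357 for the lines, and 4 to 9, 1 to 5, 6 to 10, 0 to 7, 11 to 17 and 16 to 20 lists in that order. The correlation of the field effects ran from −0.07044 to 0.006432. On arrays without spike-in signal reversed values were 0.07153 (G2/M list), −0.9957 (CDH1) and −0.1716 (HLA-DMA) in CL1-5, −0.254 (VIM) and 0.1919 (CDC25C) in CL1-0, −0.2326 (CDH1) and −0.2249 (HLA-DMA) for the average, and 0.1166 (G1/S list), −0.003782 (SLC2A3) and 0.06295 (MCM3) for the difference. With values floored at the array median they were −0.02237 (ZNF518B), −0.02237 (PROM1) and −0.1841 (CDH1) in CL1-5, 0.01348 (CFAP99) and 0.06098 (ZNF793-AS1) in CL1-0, −0.0354 (LEF1) for the average and 0.2301 (ZNF300) for the difference. With averaged probe sets EGFR was −0.03447 in CL1-0, and 0.2936 (EGFR) and −0.05833 (RPL38) for the difference; quantile normalization gave −0.01501 (ribosomal list) and −0.03039 (VIM), and spike-in arrays 0.5252 (CDH1), for the difference. Without each array in turn the interferon list ran from −0.2642 to 0.807 in CL1-5 and −0.1224 to 0.4379 for the average, and hypoxia from −0.08329 to 0.4731 and ribosomal proteins from −0.004067 to 0.4294 for the difference. CDH1 ran from −0.7317 to 0.9834, −0.5606 to 1.026, −0.2196 to 0.6379 and −1.024 to 0.6944 in CL1-5, CL1-0, the average and the difference, VIM from −0.09672 to 0.6085, −0.1526 to 0.3361, −0.03381 to 0.321 and −0.1258 to 0.5794, with −0.03179 to 0.5778 between the lines without the field, and EGFR from −0.3912 to 0.2185 for the difference. Signal near background limits the log2 changes of genes below the array median in a group, which are fitted values. The folds given as at least a value limit the effect of low signal only. They are estimates and leave out the spread over arrays. With low values raised, CDH1 differed between the lines by −2.714 without the field and −3.191 with it. Its full change was −2.59 without replicate 3 of CL1-5 without the field, and −3.01 without replicate 2 of CL1-5 with it.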

Other observations

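Genes below were chosen after their values were seen, from the fit with the replicate block, and no test of a hypothesis of their own was run. In CL1-0 the collagenase gene MMP1 was 1.14, 1.62 and 0.95 higher with the field in the 3 pairs (1.24 ± 0.17, SE, adjusted p = 0.222). From a level of 4.77 without the field, below the array median, this came to 0.60 with such values raised to the median, with 1.62 in pair 2 and 0.06 and 0.11 in the others. In CL1-0 the Notch ligand gene JAG1 was 0.85, 0.82 and 0.86 higher (adjusted p = 0.222). JAG1 changed by −0.40, −0.38 and 0.05 in CL1-5, a difference of −1.09 ± 0.17 between the lines (adjusted p = 0.343). In CL1-5 the hypoxia-induced genes HILPDA and ANGPTL4 were 0.72 ± 0.13 and 1.11 ± 0.21 higher (adjusted p = 0.299 for both), each in 3 of 3 pairs. Limma called none of them, with 0 genes called in the 4 field comparisons with the block and 1488, 467, 768 and 1002 at an unadjusted p under 0.05 in CL1-5, CL1-0, the average and the difference. Genes that moved the same way in all 6 pairs numbered 280 upward and 210 downward, 3.53% of those tested against 3.12% by chance.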
